A study of Mus musculus and Homo sapiens and unidentified plasmid with 14 samples.

How the data were processed

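The samples were 12 reporter RNA libraries and 2 plasmid libraries. Molecular inversion probes captured accelerated regions from commercial human genomic DNA and from chimpanzee DNA; the captures were cloned into a reporter vector with a minimal promoter and luciferase. Per the labels, 20 µg of constructs and 4 µg of a fluorescent reporter were transfected per 15 cm plate, cells were harvested at 48 h, and each condition had 5 transfections in each of 3 experiments. Reporter tags were amplified from polyA RNA and sequenced with paired reads of 150 bp. The 4 RNA groups (N2A human, N2A chimpanzee, SH-SY5Y human and SH-SY5Y chimpanzee) had 3 libraries each and each plasmid group had 1.

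The deposited table held a linear ratio per region and RNA library. The file does not state in words what the ratio is. It was read as reporter RNA over the plasmid library of the same species, scaled by a constant per column, because the most common value of each column and simple fractions and multiples of it recur. The deposited region file gave coordinates, nearest genes, genes in contact in germinal zone and cortical plate, marks coded 0 or 1, and the authors' human over chimpanzee fold as a ratio, which was checked to equal the mean of the 6 human columns over the mean of the 6 chimpanzee columns for 3080 of 3131 regions. The authors' notes name edgeR without a version or a role; the aligner, the assignment of tags to regions, any pseudocount and the build are not stated. For 2 regions of the ratio table the region file had no entry. Neither file gives counts or depths, so no confidence interval for counting error is given for single ratios.

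Ratios were transformed to log2 with no pseudocount, since no value was 0. A model with 1 mean per RNA group was fitted to the 12 columns with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes). Activity was the group mean tested against 0, the species difference was human minus chimpanzee within a cell line, the cell line difference was N2A minus SH-SY5Y within a species, and the interaction was the difference of the 2 species differences. All tests were two-sided, with Benjamini-Hochberg adjustment over the 3132 regions at 0.05. The residual degrees of freedom were 8, the prior ones 1.79 and the prior SD 0.699. The residual variance of a region was pooled over the 4 groups. A standard error or p of a comparison therefore does not rest on the spread of its own groups alone. Replicates share the plasmid library of their species, so the spread between them holds no error of the plasmid library. Choices named here as rules, groups or lists were fixed before the data were examined, except the groups by contact in germinal zone or cortical plate, which were not in the plan. The planned steps that need counts (normalization of counts by TMM or size factors, count models, minimum plasmid counts, and the plasmid as a group or as an offset) could not be run on ratios and were replaced by the planned fallback for ratios.

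The rule for named regions took, among called regions whose replicates all lay on one side, the 12 largest differences in each direction for species and interaction comparisons (for the interaction without the condition on replicates) and the 8 largest for activity and cell line. It added up to 3 regions, in file order, for each of PPP1R17, NPAS3, FZD8, EN1, GLI2, CUX1, PTBP2, GPC4 and AUTS2. Regions were grouped by the marks of the region file, chromosome X, 3 classes of length, contact in germinal zone or cortical plate, and nearest gene in 5 lists: genes of the literature on accelerated regions, forebrain and neurogenic transcription factors, neuronal adhesion and axon guidance genes, and 2 non-neural lists (immune; limb, muscle and heart). Each group was tested against the other regions with camera (correlation preset at 0.01, and again estimated), and calls were also counted after adjustment over the list alone. The authors' activity flag was kept apart because it was set on these samples.

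The smallest common denominator of a region and species was the smallest whole number up to 2000 for which the 6 columns, each divided by its most common value, became whole multiples of its inverse. With a shifted unit in place of the most common value, 0 regions had one. Regions with none were treated as 2000 in comparisons. Correlations across regions were set beside values simulated with no true effect, from the residual errors and from counting error of the shared plasmid libraries with the denominators read as counts. Because denominators are found from the ratios, their correlations with activity and with the species difference were also set beside 50 simulations, chosen after the data were seen, in which ratios were permuted over regions, RNA counts drawn at those ratios (at least 1) and denominators reduced anew. The fit was also tested on simulated data with 200 changed regions of 3132: at 2 log2 units it recovered 50% of activity changes, 22% of species differences, 19% of cell line differences and 0% of interactions, and 3 of 27 species calls were false.

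Alternatives were pseudocounts of 0.1 and 5, limma with a mean-variance trend, the replicate number as a block, only the groups compared, a minimum of 1.5-fold, and leaving out each library in turn. Chosen after the data were seen were subtraction of each column's median, minimum denominators of 10, 50 and 100, trend with a robust prior, and leaving out the 51 regions whose authors' fold belongs to a neighbour. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 prepared tables and figures.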

Results

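Reporter activity was measured for human accelerated regions, conserved stretches of the genome whose sequence changed unusually fast on the human lineage. Each region was captured from human and from chimpanzee genomic DNA and placed in a reporter plasmid. The human library and the chimpanzee library were each transfected into N2A cells, a mouse neuroblastoma line, and into SH-SY5Y cells, a human neuroblastoma line. Each of the 4 combinations of cell line and sequence had 3 replicates, and each of the 2 plasmid libraries was sequenced once. The deposited table gave a linear ratio for each of 3170 regions in each of the 12 RNA libraries. No region was partly missing, 38 regions had no values, and 3132 were analysed. The ratio was read as reporter RNA over the plasmid library of the same species, scaled by a constant per column. A log2 ratio of 0 is called the level of the plasmid here. Since the constants are not known, the true level of the plasmid may lie elsewhere. The plasmid libraries had no column of their own, and no counts were given, so the depth of each library is unknown. Coordinates are those of the deposited region file, whose genome build is not given in the sources used here; starts are printed counting from 1. Genes are the nearest genes of that file, given as 1 gene or as a pair.

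The median ratio lay between 1.13 and 1.28 in the 6 human columns and between 0.803 and 0.853 in the 6 chimpanzee columns. The columns had long upper tails: between 32 and 113 regions per column exceeded a ratio of 100, and the top 10 regions held 46.5% to 77.9% of a column's sum. Within a column the same value recurred in 123 to 191 regions. Divided by that value, the 6 columns of a species became multiples of 1 over a whole number for 2908 of the 3132 regions (92.8%) in the human columns and for 2957 (94.4%) in the chimpanzee columns, with whole numbers searched up to 2000. This whole number is called the smallest common denominator here; it is a property of the values and not a count of reads. Its median was 15 for human and 16 for chimpanzee sequences, and it was under 10 in either species for 1541 regions. The median standard deviation (SD) between replicates was 0.991 log2 units in those 1541 regions, 0.810 in the 1056 regions where the lower of the 2 denominators was 10 to 49, and 0.507 in the 535 regions where it was 50 or more.

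The first question was which sequences had log2 ratios above or below 0, called above or below the plasmid here. In N2A cells the human sequences of 648 regions were above the plasmid and those of 307 were below it (limma, adjusted p under the threshold of 0.05, n = 3 replicates). In SH-SY5Y cells these numbers were 562 and 231. For the chimpanzee sequences, 402 regions were above and 648 below in N2A cells, and 412 were above and 636 below in SH-SY5Y cells. Fitting only the group compared gave fewer, 295 above and 96 below for human sequences in N2A, 197 and 60 in SH-SY5Y cells, and 241 and 429 for chimpanzee sequences in N2A cells; leaving out 1 library gave totals as low as 512 and 460 for human sequences in N2A and SH-SY5Y cells. In the fit of all groups, 1185 regions were above the plasmid in at least 1 of the 4 combinations and 62 in all 4. The human sequence was above the plasmid in both cell lines for 413 regions and the chimpanzee sequence for 256.

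Among human sequences, HARsv2_1074 (chromosome 16, 82627816 to 82628095), nearest to CDH13, which encodes a cadherin without a transmembrane domain, reached a log2 ratio of 12.51 ± 0.09 in N2A cells (SD, n = 3; limma adjusted p = 9.32e-04). HARsv2_0056 (chromosome 1, 64125016 to 64125513), nearest to the receptor tyrosine kinase-like gene ROR1, reached 9.77 ± 0.11 in N2A and 9.98 ± 0.10 in SH-SY5Y cells. HARsv2_2179 (chromosome 4, 178520707 to 178520856), near LINC01098, reached 9.97 ± 0.22 and 9.72 ± 0.02. Among chimpanzee sequences, HARsv2_1954 (chromosome 3, 162738000 to 162738029), with OTOL1 and LINC01192 as nearest genes, reached 10.51 ± 0.20 in N2A and 10.65 ± 0.14 in SH-SY5Y cells. At the other end, the human sequence of HARsv2_2677 (chromosome 7, 91828714 to 91828822), with FZD1 and MTERF1 as nearest genes, was below the plasmid at -6.52 ± 0.32 in SH-SY5Y and -6.14 ± 0.49 in N2A cells. The chimpanzee sequence of HARsv2_2127 (chromosome 4, 128553630 to 128553729), next to JADE1, lay at -10.03 ± 1.36 and -10.90 ± 0.29. The smallest common denominators behind the high values were low: 3 for HARsv2_1074, 22 for HARsv2_0056 and 3 for HARsv2_2179 (human), and 2 for HARsv2_1954 (chimpanzee). All 8 regions named lowest by rule for human sequences in N2A cells had none up to 2000.

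Activity fell steadily with the denominator. Human sequences with a denominator of 1 or 2 had a median log2 ratio of 2.09 (253 regions), those at 10 to 49 had 0.22 (1238 regions) and those at 200 or more had -0.76 (344 regions). Chimpanzee sequences had 1.65 (274 regions), -0.34 (1167 regions) and -1.79 (398 regions) in the same classes. Across regions, Spearman's correlation between denominator and activity was -0.631 for human and -0.693 for chimpanzee sequences; regions are not independent replicates. The denominator is found from the same ratios, so part of this is built in: simulated ratios unrelated to the plasmid counts, a test chosen after the values were seen, gave -0.0406 and -0.0486, and -0.123 and -0.124 with plasmid counting error, if the denominators are read as counts. Subtracting each column's median moved the N2A counts to 462 above and 467 below for human sequences and to 535 and 498 for chimpanzee sequences. The same change gave 426 and 417, and 529 and 479, in SH-SY5Y cells. The subtraction sets each column's median at 0, so a near-even split is largely built in and does not place the level of the plasmid. For human sequences the direction turned with a minimum denominator in both species, chosen after the values were seen: at 10 or more, 196 were above and 280 below in N2A and 163 and 227 in SH-SY5Y cells, and at 50 or more, 34 and 222, and 36 and 210.

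The authors' own activity flag was set for 1524 regions, of which they gave 944 as higher for human and 580 as higher for chimpanzee. In the 3080 regions whose authors' fold matched their own ratios, the flag was set exactly where the mean over the SD of the 3 log2 ratios passed a value between 1.68 and 1.69 in at least 1 combination. That value is where a one-sided test on 3 replicates reaches 5% without adjustment. Of these regions 48.8% passed, and 4 independent tests would give 18.5% by chance. The tests here share plasmid libraries, so that figure is no upper limit. The flag went with low denominators. It was set for 66.9% of regions where a denominator was under 10 and 37.4% at 10 to 49. At 50 or more it was 18.3%, and at 100 or more 11.5%, so no excess was left there. The fit here found 1056 of the 1504 regions with the flag above the plasmid in at least 1 combination, and 109 of the 1576 without it. For 51 regions on chromosome X, HARsv2_3082 to HARsv2_3132, the authors' fold equalled the ratios of the next region in the table (relative tolerance 0.001), so the positions and genes of those regions may belong to a neighbour.

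The second question was whether the human and the chimpanzee sequence of a region differed. In N2A cells the human sequence gave the higher ratio in 582 regions and the chimpanzee sequence in 187 (limma, 769 of 3132 regions, 24.6%). In SH-SY5Y cells these were 558 and 204 (762 regions). The human sequence was higher in both cell lines for 390 regions and the chimpanzee sequence for 117, and 1 region was called in opposite directions. In 192 of the 390 the human sequence was above the plasmid in both lines, and in 185 the chimpanzee sequence was below it in both. In 85 of the 117 the chimpanzee sequence was above the plasmid in both lines. Over all regions the median difference, human minus chimpanzee, was 0.59 in N2A and 0.57 in SH-SY5Y cells. With each column's median subtracted, which sets the median difference near 0, 353 regions were higher for human and 302 for chimpanzee in N2A cells (53.9% human), and 354 and 284 in SH-SY5Y cells (55.5% human).

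Of the regions named by rule, HARsv2_1074 near CDH13 was higher for the human sequence by 15.19 ± 2.41 log2 units in N2A cells (standard error, SE, n = 3 against 3, limma adjusted p = 0.00204). Each SE uses the spread pooled over the 4 groups, so it can be above or below what the 2 groups compared would give. HARsv2_0802 (chromosome 14, 77717698 to 77717847), nearest to the splicing factor gene SNW1, differed by 12.02 ± 2.22 in N2A cells (adjusted p = 0.00426). Its human ratio stood near the plasmid at 0.19 ± 0.33 (SD) and its chimpanzee ratio at -11.84 ± 0.20. The latter is near the bottom of the N2A chimpanzee columns, whose lowest linear ratios were 6.75e-05 to 0.000284. The size of this difference rests on those low ratios and shrinks with a pseudocount. In SH-SY5Y cells HARsv2_0056 near ROR1 differed by 11.70 ± 1.99 (adjusted p = 0.00327) and HARsv2_2127 near JADE1 by 12.02 ± 0.66 (adjusted p = 5.25e-06). The HARsv2_2127 difference likewise rests on a very low chimpanzee ratio, at a log2 of -10.90, and shrinks with a pseudocount. Toward the chimpanzee sequence, HARsv2_1954 differed by -11.13 ± 0.52 in N2A (adjusted p = 2.37e-06) and -10.38 ± 0.52 in SH-SY5Y cells (adjusted p = 4.60e-06). HARsv2_1882 (chromosome 3, 87229780 to 87229972), nearest to the endosomal sorting gene CHMP2B, differed by -12.44 in N2A and -11.66 in SH-SY5Y cells; its log2 ratios in N2A cells were -9.53 ± 2.05 for human and 2.91 ± 0.37 for chimpanzee (SD). HARsv2_1705 (chromosome 21, 25841574 to 25841738), with GABPA and the amyloid precursor gene APP as nearest genes, differed by -14.26 ± 2.88 in N2A cells. HARsv2_0663 (chromosome 13, 93709550 to 93709696), nearest to the glypican gene GPC6, differed by -7.88 ± 1.05 in N2A cells. In SH-SY5Y cells HARsv2_1452 (chromosome 2, 132589321 to 132589516) near GPR39 differed by -10.39 ± 2.23. Of the 24 regions named in each cell line 8 were shared. Over all regions named in N2A cells, the lower of the 2 denominators had a median of 6 for human-higher and 12 for chimpanzee-higher ones. In SH-SY5Y cells these medians were 3.5 and 6.5.

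Other named regions near synaptic and developmental genes passed the test but lost it with a pseudocount of 5, which compresses low ratios. Over all comparisons, 45 of the 148 results for named regions were weaker with this pseudocount and 103 stayed the same. The regions below were picked by their genes, so the loss is not a trait of such genes. HARsv2_2585 (chromosome 7, 8379291 to 8379600) lies nearest to NXPH1; it differed by 13.75 ± 2.42 in SH-SY5Y cells, and by 2.81 with that pseudocount. HARsv2_1966 near NLGN1, a postsynaptic adhesion gene, differed by 12.28 ± 2.71 in N2A cells, and by 6.08. HARsv2_2279 near the neuronal and muscle transcription factor gene MEF2C differed by 11.92 ± 2.60 and by 7.08. HARsv2_0312 near the cortical homeobox gene EMX2 differed by 11.92 ± 3.14 and by 5.57. HARsv2_0770 near MDGA2, a regulator of synaptic adhesion, differed by 17.44 ± 3.55 in SH-SY5Y cells and by 8.22.

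**Figure D1:**
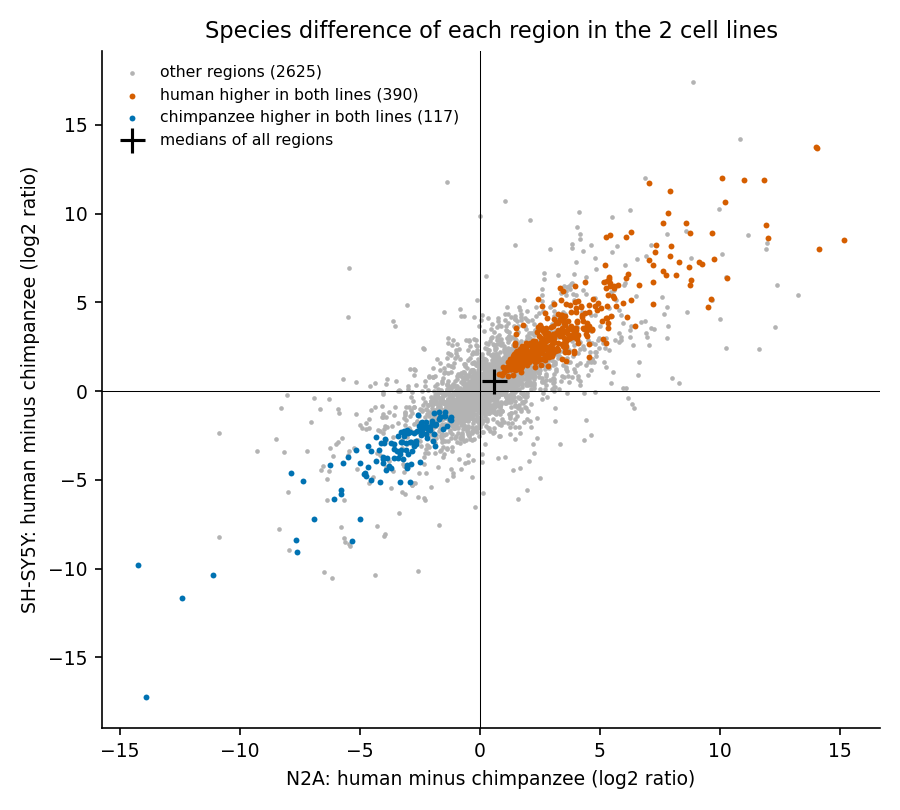
Human minus chimpanzee log2 ratio of each of the 3132 regions in N2A (x axis) and SH-SY5Y cells (y axis), each from 3 replicates per sequence. Orange points are the 390 regions higher for human in both lines, blue points the 117 higher for chimpanzee in both, grey points all others, and the cross marks the medians, 0.59 and 0.57.

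The species difference went with the 2 denominators of a region. Spearman's correlation across regions between the log2 ratio of the chimpanzee to the human denominator and the mean difference of the 2 lines was 0.695, with regions lacking a denominator set at 2000, and 0.744 in the 2832 regions with both found. Part of this is built in as well; the same simulation gave 0.0343, and 0.136 with plasmid counting error. Where the chimpanzee denominator was over 8 times the human one, the median difference was 4.23 (263 regions), and in N2A cells 156 regions were called higher for human and 0 for chimpanzee, with an adjusted p from limma. Where the human denominator was over 8 times the chimpanzee one, the median was -2.14 (246 regions), with 27 and 75 calls. In the 1410 regions whose denominators lay within 2 times of each other the median was 0.51, near that of all regions, and 147 were called higher for human and 29 for chimpanzee in N2A cells. After median subtraction these became 60 and 71 in N2A, and 52 and 64 in SH-SY5Y cells. Of the 390 regions higher for human in both lines, 273 had a chimpanzee denominator over 2 times the human one. Of the 117 higher for chimpanzee, 103 had the reverse.

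**Figure D2:**
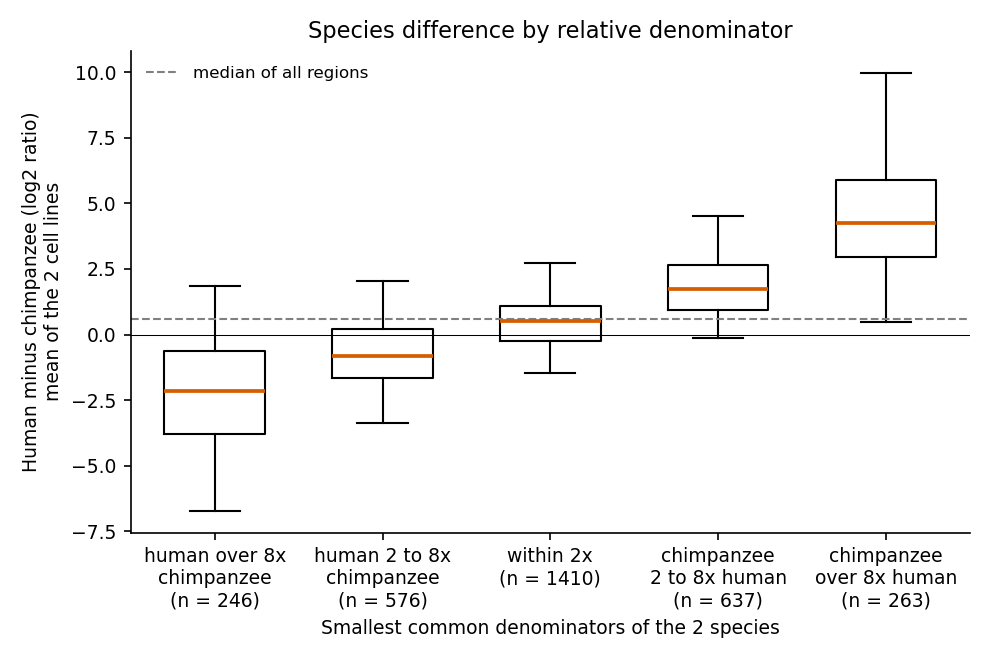
Human minus chimpanzee log2 ratio (mean of the 2 cell lines) in 5 classes of regions by the relative size of their 2 smallest common denominators; boxes span the quartiles, orange lines are medians and whiskers reach the 5th and 95th percentiles over regions. The medians run from -2.14 to 4.23, and that of the 1410 regions with like denominators is 0.51.

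Among the 837 regions whose denominators were both at least 10 and within 2 times of each other, 30 were called in both cell lines in the same direction after median subtraction, 16 higher for human and 14 for chimpanzee. Of these, 9 of the 16 and 1 of the 14 had no denominator found in at least 1 species and count as alike only because such regions were set at 2000; where both were found, 7 were higher for human and 13 for chimpanzee. This set was chosen after the values were seen, and its differences are relative to the median. HARsv2_2806 (chromosome 8, 56212502 to 56212851), nearest to CHCHD7, differed by 7.05 ± 0.79 in N2A and 6.26 in SH-SY5Y cells (SE, limma adjusted p = 3.97e-04 in N2A), with human log2 ratios of 8.03 and 8.33 against 0.39 and 1.54. Its chimpanzee replicates in SH-SY5Y cells had an SD of 1.99, with 1 value of 3.83 beside 0.43 and 0.35. HARsv2_0081 (chromosome 1, 82755235 to 82755523), near ADGRL2, which encodes the adhesion receptor latrophilin 2, differed by 4.27 ± 0.42 and 4.02. HARsv2_2690 (chromosome 7, 109864763 to 109865008), near EIF3IP1, differed by 2.88 ± 0.47 and 2.73. HARsv2_2520 (chromosome 6, 103543582 to 103544084), near the kainate receptor gene GRIK2, differed by 1.82 and 1.53. Toward the chimpanzee sequence, HARsv2_1189 (chromosome 18, 37669138 to 37669407), near LINC00669, differed by -6.01 ± 1.89 and -9.27 (limma adjusted p = 0.0481 in N2A), with an SD of 4.99 over the chimpanzee replicates in N2A cells. Its SE pools the 4 groups and so understates that spread. HARsv2_0362 (chromosome 11, 30571370 to 30571408), nearest to MPPED2, differed by -6.90 ± 1.54 and -5.06, with an SD of 4.00 over the chimpanzee replicates in SH-SY5Y cells. HARsv2_1541 (chromosome 2, 181468847 to 181469148), nearest to the integrin gene ITGA4, differed by -3.74 ± 0.68 and -2.78. HARsv2_2214 (chromosome 5, 5374048 to 5374407), which contacts the metalloprotease gene ADAMTS16 in cortical plate in the region file, differed by -2.30 ± 0.31 and -1.72. HARsv2_2476 (chromosome 6, 69296458 to 69296679), nearest to the brain adhesion receptor gene ADGRB3, differed by -2.19 and -2.09. HARsv2_0961 (chromosome 16, 5458079 to 5458166), near EEF2KMT, differed by -1.82 and -2.16. HARsv2_2544 near the transcriptional coactivator gene EYA4 differed by -1.76 and -1.88.

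**Figure D3:**
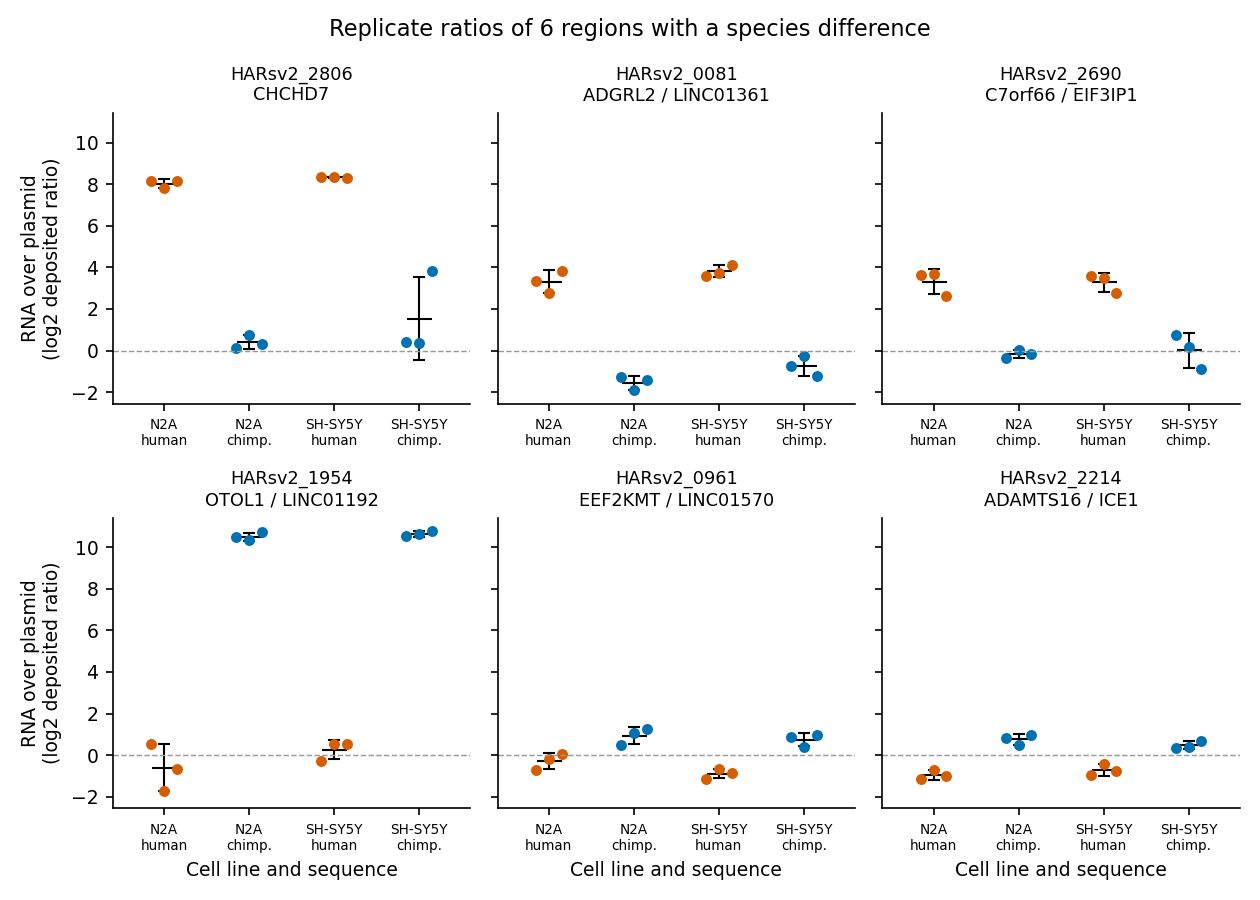
Log2 ratio of reporter RNA over plasmid in each of the 3 replicates (points; orange human, blue chimpanzee) with the mean and SD (bars) for 6 regions, by cell line and sequence. The human sequences of HARsv2_2806, HARsv2_0081 and HARsv2_2690 lay above the chimpanzee sequences in every replicate, and the chimpanzee sequences of HARsv2_1954, HARsv2_0961 and HARsv2_2214 above the human ones.

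Regions near genes named before the data were seen gave a mixed picture. NPAS3, a brain transcription factor gene long tied to accelerated regions, had 20 regions; of the first 3 in the file, HARsv2_0731 (chromosome 14, 32948546 to 32948898) was higher for the chimpanzee sequence, by -2.51 ± 0.73 in N2A (limma adjusted p = 0.0318) and -3.99 ± 0.73 in SH-SY5Y cells (adjusted p = 0.00442). HARsv2_0730 did not pass, at 1.02 (adjusted p = 0.159) and 1.05 (0.151), nor did HARsv2_0732 at 4.00 (0.517) and 7.29 (0.236). PTBP2, a neuronal splicing regulator gene, had 3 regions; HARsv2_0105 differed by -5.49 ± 1.06 (adjusted p = 0.00519) and -3.69 ± 1.06 (0.0313), while HARsv2_0106 at 6.10 (0.0730) and 0.19 and HARsv2_0107 at -0.29 and -3.88 did not pass. Near the hedgehog pathway gene GLI2, HARsv2_1444 differed by -3.41 ± 0.93 in N2A (0.0253) and -2.52 in SH-SY5Y cells (0.0783), and HARsv2_1443 did not pass in either line (1.02 and -1.73). HARsv2_1442 near the homeobox gene EN1 differed by 1.38 ± 0.37 in N2A cells (0.0238), a call that ended when the median shift was taken out (0.79, adjusted p = 0.175), and by 0.78 in SH-SY5Y cells (0.154). AUTS2 had 9 regions. Of the first 3 in the file, HARsv2_2665 differed by -5.74 ± 1.69 in N2A (0.0343) and -2.62 in SH-SY5Y cells (0.281), while HARsv2_2664 (-1.20 and -1.23) and HARsv2_2666 (1.16 and 0.48) did not pass. HARsv2_3147 near the glypican gene GPC4 differed by 0.19 and -0.68, neither past the test. PPP1R17, FZD8 and CUX1 were nearest to 0 regions. The denominators of the called regions were unequal: 63 human and 7 chimpanzee for HARsv2_0731, 65 and 2 for HARsv2_0105, 62 and 8 for HARsv2_1444, and 130 and 4 for HARsv2_2665. With a pseudocount of 5 the N2A calls of HARsv2_0731 (-0.71, adjusted p = 0.0691) and HARsv2_2665 (-0.93, 0.236) ended, and those of HARsv2_1444 in N2A and HARsv2_0105 in SH-SY5Y cells ended when some single libraries were left out.

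Ratios agreed across regions far more between the cell lines than between the species. The 2 lines share the plasmid library of a species and the 2 species share none. The contrast therefore does not separate the activity of a sequence from its plasmid. Human activity in N2A and SH-SY5Y cells had a Pearson correlation across regions of 0.783 and chimpanzee activity 0.816, and the species difference in the 2 lines 0.776. Within a cell line, human and chimpanzee activity correlated at 0.103 in N2A and 0.0873 in SH-SY5Y cells. The 390 regions higher for human in both lines compare with 103.7 for independent calls, and the 117 higher for chimpanzee with 12.2, though calls are not independent here because both lines share the plasmid library of each species. Simulation with no true effect, with counting error of the shared plasmids set by the denominators, gave correlations of 0.269 for human activity, 0.268 for chimpanzee activity and 0.269 for the species difference. It does not model the fall of activity with the denominator. The correlation between species rose from -0.138 where a denominator was under 10 to 0.0314 at 10 to 49 and 0.396 at 50 or more (535 regions), and it was 0.558 in the 1410 regions with like denominators. Given both log2 denominators, the partial correlation was 0.296. Regions are not independent replicates, and no p is given for these correlations.

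Regions were then grouped by the marks of the region file, by length, by chromosome and by gene lists fixed beforehand. None of the 15 groups stood apart from the other regions in any of the 9 comparisons by limma's camera test (135 tests; lowest adjusted p = 0.930 with the preset correlation and 0.807 with an estimated correlation, 0 unadjusted p under 0.05 in either). With minimum denominators, chosen after the values were seen, none passed either, but the preset correlation gave 2 unadjusted p under 0.05 at 10 or more (lowest adjusted p = 0.223) and 6 of 117 at 100 or more (lowest adjusted p = 0.0740); the estimated correlation gave 0 in both. Of 1586 regions with fetal brain acetylation, 305 were higher for human and 97 for chimpanzee in N2A cells (308 and 97 adjusted over the list alone) and 296 and 107 in SH-SY5Y cells (305 and 111 alone). Of 796 with adult brain acetylation these were 146 and 55 (147 and 56 alone), and 159 and 50 (164 and 52 alone). The ChIP marks gave 65 and 23 of 348 regions for bulk tissue, 73 and 25 of 395 for neural progenitors and 52 and 16 of 289 for neurons in N2A cells; adjusted over the list alone they gave 67 and 26, 73 and 25, and 44 and 14. In SH-SY5Y cells they gave 69 and 21, 69 and 29, and 54 and 21 (72 and 23, 70 and 31, and 57 and 22 alone). Regions in contact with a gene in germinal zone (509) gave 85 and 32 in N2A and 84 and 30 in SH-SY5Y cells (76 and 31, and 80 and 29, adjusted over the list alone). Those in contact in cortical plate (448) gave 84 and 29, and 67 and 26 (84 and 29, and 63 and 24 alone). Chromosome X (97 regions) gave 15 and 7, and 18 and 6 (14 and 7, and 18 and 6 alone). By length, the longest 1043 regions gave 208 and 55 in N2A cells, the middle 1043 gave 180 and 67 and the shortest 1044 gave 194 and 64 (211 and 55, 177 and 66, and 194 and 64 alone).

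Near neuronal adhesion and axon guidance genes, 39 of 157 regions were higher for human and 8 for chimpanzee in N2A cells (42 and 9 adjusted over the list alone) and 34 and 9 in SH-SY5Y cells (34 and 9 alone). They include HARsv2_1074 near CDH13 and HARsv2_1966 near NLGN1, higher for human, and HARsv2_1887 near the ephrin receptor gene EPHA3, higher for chimpanzee in SH-SY5Y cells (-17.24; the EPHA3 call ended with a pseudocount of 0.1, at -9.14, adjusted p = 0.0686). Near forebrain and neurogenic transcription factors, 10 of 72 regions were higher for human and 3 for chimpanzee in each line (5 and 2 in N2A, 9 and 3 in SH-SY5Y, adjusted over the list alone). Near genes of the literature on accelerated regions, 5 and 5 of 61 passed in N2A (5 and 5 alone) and 8 and 5 in SH-SY5Y cells (7 and 5 alone). The non-neural limb, muscle and heart list gave 7 and 1 of 16 in N2A (8 and 1 alone), with a median difference of 1.39, and 4 and 1 in SH-SY5Y cells (4 and 1 alone), with 1.09. The immune list had 1 region, which did not pass in any comparison (0 adjusted over the list alone). The authors' flag, which was set on these samples and so is not independent evidence, gave 599 above and 42 below the plasmid of 1524 for human sequences in N2A cells (673 and 50 adjusted over the list alone).

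The last question was whether activity, or the species difference, depended on the cell line. For human sequences 2 regions differed between N2A and SH-SY5Y cells and for chimpanzee sequences 4 (limma; 176 and 160 regions at an unadjusted p under 0.05). HARsv2_2701 (chromosome 7, 115286691 to 115287532), near TFEC, a gene of the MITF family of transcription factors, had human log2 ratios of 4.26 ± 0.21 in N2A and 0.84 ± 0.25 in SH-SY5Y cells (SD, n = 3), a difference of 3.41 ± 0.31 (SE; adjusted p = 0.00228). The human sequence of HARsv2_2748 (chromosome 8, 911274 to 911471), near ERICH1-AS1, was lower in N2A cells by -8.04 ± 1.01 (adjusted p = 0.0212). For chimpanzee sequences, HARsv2_0451 (chromosome 11, 121930499 to 121930701), near the sorting receptor gene SORL1, was higher in N2A by 5.21 ± 0.53. HARsv2_1351 (chromosome 2, 35912517 to 35912674), near LINC01320, was lower by -6.06 ± 0.48, HARsv2_0446 near the adhesion gene DSCAML1 by -2.38 ± 0.35 and HARsv2_0931 near the neurotrophin receptor gene NTRK3 by -2.35 ± 0.34. The species difference itself differed between the lines in 4 regions, HARsv2_1351 (7.55 ± 0.68, adjusted p = 0.00221), HARsv2_2701 (3.57 ± 0.43, 0.0151), HARsv2_0451 (-5.97 ± 0.75, 0.0151) and HARsv2_2748 (-9.63 ± 1.42, 0.0427), out of 157 at an unadjusted p under 0.05. With no true effect, a share of 0.05 of the 3132 regions would have such a p. The 176, 160 and 157 regions lie near that number. In simulated data the same test recovered 19% of cell line differences of 2 log2 units and 0% of interactions of that size, so smaller differences were mostly not detectable at this spread. HARsv2_1351 kept both its calls in every alternative that included it. Its denominators were too low for any minimum denominator to include it, so those alternatives did not test it. HARsv2_2701 lost its interaction call with a mean-variance trend, and HARsv2_2748, HARsv2_0451, HARsv2_0446 and HARsv2_0931 each lost a call in at least 1 alternative.

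**Figure D4:**
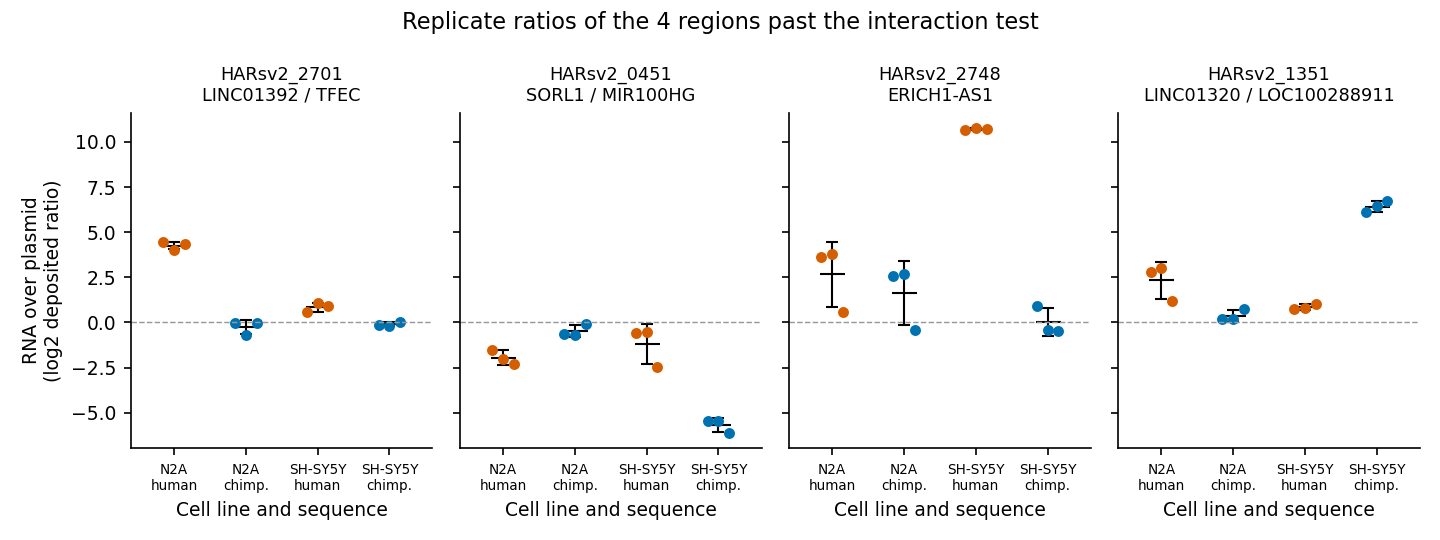
Log2 ratio of reporter RNA over plasmid in each of the 3 replicates (points; orange human, blue chimpanzee) with the mean and SD (bars) for the 4 regions whose species difference differed between the cell lines. HARsv2_2701 was highest for the human sequence in N2A cells, at 4.26, and HARsv2_1351 was highest for the chimpanzee sequence in SH-SY5Y cells, at 6.42.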

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

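The test of unequal plasmid representation, the test limited to regions with denominators of 50 or more, the divisions of regions by how alike their denominators are and the simulation of denominators were chosen only after the result was seen. The interaction test singled out 4 regions whose species difference differed between the cell lines. The difference of differences, N2A minus SH-SY5Y, was 7.55 for HARsv2_1351, 3.57 for HARsv2_2701, -5.97 for HARsv2_0451 and -9.63 for HARsv2_2748. The denominators were 2 and 2 for HARsv2_1351 and 2 and 3 for HARsv2_2748 (human and chimpanzee), 15 and 150 for HARsv2_0451, and 38 and 63 for HARsv2_2701. Chance was not excluded for the count as a whole: 94 of 100 splits of the libraries, the real one included, gave at least the 4 regions found, and the highest other split gave 17. For the cell line comparisons, 10 of 10 splits gave at least the 2 regions found for human sequences (highest other 10), and 9 of 10 gave at least the 4 found for chimpanzee sequences (highest other 13). The highest of these splits called several times the real counts but still few regions, so a structure among the libraries that the groups do not follow is not excluded. For the species comparisons the real split was 1 of 10 in each cell line, at 769 and 762 regions against at most 1 in the other splits; with 10 splits, as in the cell line comparisons, a share under 0.05 cannot be reached.

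The first pattern weighed was that species differences were large and recurred in both cell lines, while the 2 species' ratios agreed poorly. Counting error of the plasmid libraries alone is argued against, if the denominators are read as counts: in regions with denominators of 50 or more its simulated covariance between the lines was 0.0170 of the observed one (0.0330 against 1.94, bootstrap interval 1.40 to 2.61). Few plasmid reads behind many ratios remains open as a part, since the SD of the species difference was 1.74 times larger where a denominator was under 10 than at 50 or more, and the correlation between species was 0.534 higher in the latter. Unequal plasmid representation of the 2 species may account for part of the pattern: the log2 ratio of the denominators correlated with the difference at a Spearman's rho of 0.695, against 0.136 built in by finding denominators from the same ratios (simulated with plasmid counting error, if denominators are read as counts), and the SD of the difference fell from 2.43 to 1.66 after regression on the denominators. Sequence changes between human and chimpanzee stay open as an untested explanation for what is left, as do effects of amplification and of single tags, since each species has 1 plasmid library that both cell lines share.

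The second pattern was that more regions were higher for the human than for the chimpanzee sequence. A constant scaling difference between the columns of the 2 species cannot be told apart from a real shift over all regions, since subtracting each column's median removes both and sets the median difference near 0, so that the shares of human-higher calls that followed, 53.9% in N2A and 55.5% in SH-SY5Y cells, come largely from the subtraction and do not decide. The most common value of a column, read as its unit, was 1.36 to 1.83 in human and 1.08 to 1.14 in chimpanzee columns. The median ratio was 1.13 to 1.28 in human and 0.803 to 0.853 in chimpanzee columns. In both species the medians lay below the units by similar factors. If the unit is the scaling constant of its column, that constant may carry most or all of the median difference. The fit was not repeated on ratios divided by their units, so its share in the excess of human-higher calls was not tested. In regions with denominators of 50 or more a constant shift alone is argued against by the calls after median subtraction. In N2A cells 76.1% (67 of 88, exact 95% interval 65.9% to 84.6%) were higher for human, and in SH-SY5Y cells 77.0% (67 of 87, 66.8% to 85.4%). These intervals treat regions as independent draws, though all share 1 plasmid library per species. They hold no error of the libraries or of the column scaling. Whether unequal denominators account for that 76.1% stays open: in the same fit, regions with denominators within 2 times of each other had 19 human-higher and 13 chimpanzee-higher calls in N2A (59.4%; 40.6% to 76.3%) and 14 and 14 in SH-SY5Y cells, against 48 and 8, and 53 and 6, where they were further apart, while regions with like denominators called in both lines after median subtraction over all regions were 16 and 14 at 10 or more (7 and 13 where both were found) and 10 and 4 at 50 or more (1 and 3). Among the like ones in the same fit, the human excess was seen only where a species had no denominator found up to 2000, so that likeness is not known (11 and 3; 12 and 1), and not where both were found (8 and 10; 2 and 13); the numbers are small, and a biological difference between the sequences remains untested.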

How the results depend on the processing

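The minimum denominators, median subtraction, robust prior and omission of the displaced regions were tests chosen only after the result was seen. Values run in the order N2A human, N2A chimpanzee, SH-SY5Y human and SH-SY5Y chimpanzee for activity, N2A and SH-SY5Y for the species difference, human and chimpanzee for the cell line difference, then the interaction; the cause of each change was not tested unless stated. With minimum denominators the counts fell with the number of regions tested while the share called, for the species difference in N2A cells, went from 24.6% of all regions to 21.9% at 10 or more, 38.5% at 50 or more and 53.2% at 100 or more (15.1% and 16.4% at 10 and 50 or more after median subtraction), and for human activity in SH-SY5Y cells from 25.3% to 24.5%, 46.0% and 63.4%. Without median subtraction the species calls at 50 or more were 194 higher for human and 12 for chimpanzee in N2A (94.2% human, against 75.7% over all regions) and 204 and 17 in SH-SY5Y cells. A denominator of at least 10 gave 476, 644, 390 and 652 (above and below: 196 and 280, 94 and 550, 163 and 227, 101 and 551, so most calls for human sequences turned to below), species 349 and 362, cell line 1 for human, and interaction 2. At least 50 gave 256, 349, 246 and 340 (34 and 222, 22 and 327, 36 and 210, 22 and 318), then 206 and 221, 0 and 1, and 0. At least 100 gave 206, 235, 210 and 235, then 176 and 182, 1 for human, and 0. Median subtraction with at least 10 gave 549, 546, 519 and 546, then 240 and 236, 1 and 2, and 2; with at least 50 it gave 295, 311, 309 and 317, then 88 and 87, 0 and 1, and 0. Fitting only the groups compared gave activity counts of 391, 670 and 257 (the first 3 groups) and cell line counts of 4 and 7. Of the results for named regions, it made 44 weaker and left 100 the same. A pseudocount of 5 gave 494 for the SH-SY5Y species difference, 9 and 7 for the cell line and 7 for the interaction; 0.1 gave 1 for the cell line in chimpanzee sequences. The mean-variance trend, with and without a robust prior, gave 1 for the cell line in human sequences and 2 for the interaction. The replicate number as a block gave 753 and 741 for the species difference and 2 for the cell line in chimpanzee sequences; 18 pairs of same-numbered libraries had residual correlations from -0.0192 to 0.130, and in 13 of the 18 the correlation was highest with the own number, so a weak pairing is not excluded. Median subtraction alone, the 1.5-fold minimum and the omission of displaced regions left each of the 9 total counts within 1.5 times. Median subtraction nevertheless moved the calls between directions. Human-higher and chimpanzee-higher species calls went from 582 and 187 to 353 and 302 in N2A, and from 558 and 204 to 354 and 284 in SH-SY5Y cells.

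Leaving out 1 library at a time gave activity counts of 512 to 951, 704 to 1067, 460 to 787 and 693 to 1052, species counts of 564 to 776 and 490 to 771, cell line counts of 1 to 22 and 2 to 15, and interaction counts of 3 to 19. Activity of human sequences in N2A cells fell to 554 without its replicate 1 and 512 without replicate 2, and in SH-SY5Y cells to 500 and 460 without replicates 1 and 2. Without SH-SY5Y chimpanzee replicate 1, its activity count was 693 and the SH-SY5Y species count 490. The cell line count for human sequences was 13, 4 and 10 without N2A human replicates 1, 2 and 3, 4 without N2A chimpanzee replicate 3, 10 and 22 without SH-SY5Y human replicates 1 and 3, and 1 without SH-SY5Y chimpanzee replicate 3. For chimpanzee sequences it was 9, 9 and 10 without N2A chimpanzee replicates 1, 2 and 3, 7 and 15 without SH-SY5Y chimpanzee replicates 1 and 3, and 2 without N2A human replicate 1 or any SH-SY5Y human replicate. The interaction count was 13 and 10 without N2A human replicates 1 and 3, 7, 9 and 12 without N2A chimpanzee replicates 1, 2 and 3, 9 and 19 without SH-SY5Y human replicates 1 and 3, and 8 and 7 without SH-SY5Y chimpanzee replicates 1 and 3.

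Correlations across regions with Spearman's rho, at least 100 and at least 10 were 0.758, 0.558 and 0.736 for the species difference between lines, 0.821, 0.749 and 0.754 for human activity between lines, 0.173, 0.362 and 0.178 between species in N2A cells, and 0.180, 0.344 and 0.144 in SH-SY5Y cells; for chimpanzee activity the first 2 were 0.842 and 0.774. Of 148 results for named regions, 64 kept direction and side of the threshold in every alternative that included them, and none of the 129 called ones reversed in any. The rule mostly took the largest called differences with all replicates on one side, which these alternatives could hardly reverse. The lack of reversals among called results is therefore no measure of their stability. The 13 reversals were in uncalled regions: HARsv2_0106 in SH-SY5Y cells (-0.34 with median subtraction, alone or with at least 10; -2.05 without SH-SY5Y human replicate 3; -1.43 without SH-SY5Y chimpanzee replicate 2), HARsv2_0107 in N2A cells (0.31 without N2A human replicate 1; 0.060 without N2A chimpanzee replicate 1), HARsv2_1443 in SH-SY5Y cells (0.94 without SH-SY5Y chimpanzee replicate 1), HARsv2_3147 (-0.41 in N2A with median subtraction; -0.18 without N2A chimpanzee replicate 2; 0.26 in SH-SY5Y without SH-SY5Y human replicate 3) and HARsv2_2666 in SH-SY5Y cells (-0.052 with median subtraction, alone, with at least 10 and with at least 50). Over the libraries left out, these ranged from -2.05 to 1.69 for HARsv2_0106, -0.60 to 0.31 for HARsv2_0107, -3.15 to 0.94 for HARsv2_1443, and -0.18 to 0.38 and -1.18 to 0.26 for HARsv2_3147. Alternatives that need counts (library totals, TMM or size factors, count models, minimum plasmid counts and the plasmid as an offset) were not run because the files hold ratios. Depth is not given, so what it limits cannot be computed.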

Other observations

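Regions with denominators of 50 or more in both species were looked at separately, a set chosen only after the result was seen, as were the tests on it. After median subtraction 61 of these 535 regions were called in both cell lines in the same direction, 54 higher for human and 7 for chimpanzee. Where the denominators were over 2 times apart these were 43 and 2, where they were alike and found in both species 1 and 4, and where they count as alike with none found in at least 1 species 10 and 1. The chimpanzee sequence was below the plasmid in both lines in 53 of the 54. The human sequence was above it in both lines in 3 and below it in both in 13. The largest were HARsv2_0802 near SNW1 (11.43 in N2A and 8.09 in SH-SY5Y cells; SD of the chimpanzee replicates 5.96 in SH-SY5Y), HARsv2_1075 near LOC101928446 (7.39 and 7.66; SD of the chimpanzee replicates 2.39 and 2.81) and HARsv2_2053 (chromosome 4, 56938292 to 56938518), near REST, the gene of a repressor of neuronal genes (6.63 and 5.60; SD of the human replicates 3.29 in SH-SY5Y). HARsv2_2914 (chromosome 9, 2623241 to 2623780) near VLDLR, a reelin receptor gene, differed by 2.80 and 3.49. Among the 7 higher for chimpanzee, HARsv2_2088 (chromosome 4, 82128599 to 82129349) near HNRNPD differed by -2.77 and -2.64 and HARsv2_1579 (chromosome 2, 208108273 to 208108409) near PLEKHM3 by -2.49 and -1.75, and in 5 of the 7 the chimpanzee sequence was above the plasmid in both lines.

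Within this set, regions near listed genes included HARsv2_0462 near NTM (1.83, mean of the 2 lines), HARsv2_1862 near the axon guidance receptor gene ROBO1 (1.73), HARsv2_1607 near EPHA4 and PAX3 (1.73), HARsv2_0748 near NPAS3 (1.87), HARsv2_1678 near TSHZ2 (1.65) and HARsv2_1393 near LRRTM4 (1.00), all higher for human. All 6 had no human denominator up to 2000 and a chimpanzee one of 194 to 695, so they belong to a class of regions described below, whose median difference was 1.69 before median subtraction and 1.11 relative to all regions; the 6 values are after median subtraction. Adhesion and axon guidance genes were nearest to 4 of the 61 regions against 2.39 expected, and none of the 15 groups was enriched (Fisher's exact test, lowest p = 0.146, lowest adjusted p = 0.850).

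In 99 regions with no denominator up to 2000 in either species, the median species difference was 0.57 (quartiles 0.50 and 0.65), and the 2 species' activities correlated across regions at a Pearson's r of 0.492. In 87 regions with none for human and one of 100 to 2000 for chimpanzee, the median difference was 1.69, and 46 of the 87 lay between 1.5 and 2.5. In the 36 regions with the reverse, 2 lay in that range and the median was 0.11. No explanation for the cluster was tested. Mean ratios over 100 occurred for 47 combinations of region and species; 16 of them had a denominator of up to 2 and 3 had one of 50 or more.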
